A study of Mus musculus with 12 samples.

How the data were processed

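The series holds 12 RNA-seq libraries of brain tissue from mice at postnatal day 0. Per the labels, they form 4 groups of 3 replicates each: cortex and subcortex of wild-type (WT) mice and of mice with a vascular knockout of Reck (vKO). The labels write the vKO genotype as Reck flex2/Δex1 with Tie2Cre, a Cre line active in endothelial and blood lineages, and the strain as mixed. Tissue was flash frozen, total RNA was purified with TRIzol and RNeasy columns, and libraries were made with a TruSeq stranded total RNA kit, per the labels' protocols. The labels do not say whether replicate numbers mark single animals, or whether the cortex and the subcortex of one number come from one brain.

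The submitters' processing notes name the mm10 build, HISAT2 2.0.1, Cufflinks 2.2.1 and Cuffdiff, with no version for the last and no account of the order of the steps. The deposited files are 2 tables of the authors' own comparisons, 1 per tissue, each with 23983 entries. Their columns name the groups by letters, of which W was read as WT and M as vKO, since the labels have only these genotypes in each tissue. Each entry holds 1 FPKM value per group (fragments scaled by transcript length and by mapped fragments), computed by the authors from all replicates of the group, per the file headers. The log2 column of the authors' deposited table is the log2 of the vKO over the WT value. Its test statistic, a score with no fixed range per the file headers, was not used further. The p-value and q-value columns are the authors' own test, per the file headers, and the deposited q-values differed by at most 5.2e-07 from a Benjamini-Hochberg adjustment over the genes marked as tested.

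No value per replicate was used here, so no SD, no test over samples and no interaction between tissue and genotype was computed. The depth of the libraries is unknown from these files, and the FPKM values do not give it. The design fixed before the data were examined had foreseen this case: the authors' q-values under 0.05 were counted as theirs, and a gene is written as having risen or fallen only where that q-value passed. The lowest p-value that the deposited test lists is 5e-05, and 843 cortex calls and 66 subcortex calls stand at it. The test covered 13594 entries in cortex and 13735 in subcortex. The rest were marked as too low (10190 and 10046), as lacking data (192 and 190) or as too deep (7 and 12), and took part in no count. An FPKM of 0 can be a failed estimate in such entries, so it is given as listed at 0. Of the symbols, 27 in each table had been turned into dates by a spreadsheet, and 4 entries with a repeated date symbol were left out. The log2 column held error text in 690 and 348 cells, all of them with vKO at 0, so log2 ratios were recomputed from the FPKM values.

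The log2 ratio used throughout is log2((vKO FPKM + 1)/(WT FPKM + 1)), which understates the change of genes with low values. The 1.5-fold minimum among the alternatives is instead on the FPKM ratio without a pseudocount, except where 1 added is stated. Positive ratios mean higher in vKO. Before the data were examined, 29 gene lists with 369 members were fixed, for endothelial and mural cells, blood and immune cells, neural cell types and pathways. Of the members, 359 were found by symbol, 3 through an entry shared with a neighbouring gene and 5 by an older symbol (Gpr124 for Adgra2, Ppap2b for Plpp3), and 2 globin-related genes were not found. For each list the median log2 ratio over the tested members was set against 10000 random lists of the same size, drawn from 20 bins of mean expression. This percentile describes these group values and is no p-value. Members called are counted over all tested genes, and again with the authors' p-values adjusted over the list alone. Tissues were compared through the overlap of the calls with the number that independent lists would share, and through the correlation of log2 ratios across genes with an FPKM of at least 1 in at least 1 group, which has no p-value because genes are not independent replicates.

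Named genes follow a rule fixed before the data were examined: Reck and its receptor complex list, per tissue the 8 largest rises and 8 largest falls among the authors' calls with an FPKM of at least 1 in at least 1 group, leaving out predicted gene models and sex-linked genes, and for each list up to 4 called members with the lowest q, or otherwise the 2 with the highest FPKM. Genes outside the rule were picked after their values were seen, and this is said where they appear.

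Several steps were chosen after the data were seen. Transcript length and GC content came from the GENCODE M21 annotation of the same build, as the longest protein-coding transcript where there is one. The annotation the authors used is not given in the sources used here. That choice was made for the search for copies, after a first correlation with length had been seen. A trend with length and GC was removed by subtracting the median ratio of 100 cells of length and GC, and lists were also matched on expression, length and GC together (90 cells). The difference of the pan-endothelial and barrier medians was also taken with the trend removed, and given an interval by resampling the members of both lists 10000 times. Near-identical copies were searched with minimap2 2.31, as another gene's transcript at 95% identity over at least 300 bases or 50% of the transcript. This criterion was picked after 8 had been compared on these data. Over the 8, the share of tested cortex genes with a copy ran from 5.54% to 20.2%, that among genes higher in vKO cortex from 15.8% to 36.4%, and that among lower ones from 1.78% to 10.0%. Sets without genes of X and Y, families taken from symbol patterns, and lists of 4 genes that escape X inactivation and 4 Y-linked genes were added in the same way.

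The procedure was tested on simulated data made from each tissue's own length and GC trend, with the residual ratios reassigned among genes of like expression. Shifts of 1 log2 unit up or down in 200 genes came back after removal of the trend, measured from those residuals, as median shifts of 0.996 and -0.998 in cortex (13412 genes) and 1.00 and -0.998 in subcortex (13561 genes). The simulated trend was made of the same cell medians that the removal subtracts, so recovery near the set shift was built in. Of 200 null lists of 15 long genes, 46.5% fell outside the central 95% of expression-matched lists in simulated cortex, and 6% once length and GC were matched. In simulated subcortex these shares were 4% and 4.5%. Lists shifted by 0.5 lay above the central 95% of lists matched on all 3 properties in 100% of cases in both tissues, with 1000 draws per list. Residuals were reassigned gene by gene, so the co-expression of genes in real lists was not simulated. The shares given here need not hold for lists of co-expressed genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used, with matplotlib 3.10.9 for the figures.

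The alternatives were other q thresholds, a fold minimum, a filter on FPKM, a pseudocount of 0.1, the authors' own ratio without a pseudocount, and the steps listed above. Their effect is given in the closing section.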

Results

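RNA of whole cortex and subcortex was measured in wild-type (WT) mice and in mice labelled as lacking Reck in vascular cells (vKO) at postnatal day 0, in 4 groups of 3 libraries each. The deposited values are 1 FPKM per gene and group, so no spread between replicates can be given for any value, and the depth of the libraries is unknown. Calls of higher or lower genes rest on the q-values under 0.05 of the authors' deposited table for each tissue. A gene is said to have risen or fallen only where it was called there. Changes are log2((vKO FPKM + 1)/(WT FPKM + 1)), and positions are those of mm10 with starts counted from 1. For each gene list, the median ratio is followed by its percentile among random lists matched on expression, and then by that among lists matched on expression, transcript length and GC content.

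Reck, the targeted gene (chromosome 4, 43875530 to 43944806, 21 exons in its main annotated transcript), stood at 2.91 FPKM in WT and 3.23 in vKO cortex, with a q-value of 0.639 in the authors' deposited table. In subcortex it stood at 2.37 and 3.49 FPKM, with a q-value of 0.333 in the authors' deposited table. Tie2-Cre acts in a part of the cells, the alleles named in the labels affect a part of the gene, and the FPKM covers the whole gene in whole tissue, so these values do not check the labels. Reck acts with Gpr124 as a co-receptor for Wnt7a and Wnt7b on endothelial cells. In cortex Gpr124 fell from 3.84 to 2.35 FPKM (-0.53) and the Wnt co-receptor Lrp6 from 17.2 to 11.1 (-0.58), by the authors' deposited table. With the trend of ratios with transcript length and GC content removed these ratios were -0.21 and -0.12. Of the 10 genes of this receptor complex these were the 2 called in cortex, and adjusted over the list alone they were again 2 lower and 0 higher. The ligands were not called in cortex: Wnt7a had 9.69 FPKM in WT and 8.34 in vKO, and Wnt7b had 21.2 and 26.3. The median of the complex was -0.00 in cortex (percentiles 52.3 and 89.8). In subcortex none of the 10 was called in the authors' deposited table, and the median was 0.07 (percentiles 84.0 and 77.8). Adjusted over the list alone 2 were higher there: Fzd4, with a p-value of 0.0061 in the authors' deposited table, and Reck itself, with 0.0072. By that count the targeted gene is higher in the libraries labelled vKO, the opposite of a loss of its transcript, though a count over whole tissue and the whole gene does not check the deletion.

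The comparison of vKO with WT cortex asks how the RNA of the cortex differs in mice of the vKO genotype. Tie2-Cre is active in blood lineages too, and the labelled genotype includes a Δex1 allele, so the comparison does not isolate loss from vessels. Genes of the blood-brain barrier were lower in vKO cortex, genes of fenestrated endothelium were higher, and globin, microglial, macrophage, hypoxia, glycolysis and cell cycle genes were higher. Hmox1, the haem-degrading enzyme haem oxygenase (chromosome 8, 75093618 to 75100593), rose from 2.04 to 59.7 FPKM (4.32). Slc38a5, an amino acid transporter of brain endothelium (chromosome X, 8271381 to 8280176), fell from 6.79 to 0.695 FPKM. Of 13594 tested genes, 2645 were called in cortex by the authors' deposited table, 1108 higher and 1537 lower, and 1520 of them changed at least 1.5-fold in the FPKM ratio without a pseudocount.

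Of the 21 genes of barrier endothelium, 10 fell and 1 rose in cortex by the authors' deposited table, and adjusted over the list alone 14 were lower and 1 higher. The median was -0.39 (percentiles 0 and 0), and -0.31 with the length and GC trend removed. Cldn5, the claudin of brain endothelial tight junctions (chromosome 16, 18776847 to 18778262), fell from 46.8 to 24.6 FPKM (-0.90). The arginine transporter Slc7a1 fell from 14.1 to 6.37 (-1.03) and the thyroid hormone transporter Slco1c1 from 14.2 to 6.70 (-0.99). Slc2a1, the glucose transporter of the barrier, named here after its value was seen, was not called in cortex, at 16.9 FPKM in WT and 13.6 in vKO. Of the 10 genes of fenestrated and peripheral endothelium, 5 rose and 2 fell by the authors' deposited table (6 and 3 adjusted over the list alone), and the median was 0.68 (percentiles 100 and 100). Plvap, the protein of fenestral diaphragms (chromosome 8, 71497753 to 71511769), rose from 1.20 to 4.20 FPKM (1.24), Emcn from 3.30 to 8.03 (1.07) and Cd34 from 9.07 to 16.3 (0.78), while Vwf fell from 4.08 to 1.65 (-0.94).

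**Figure D1:**
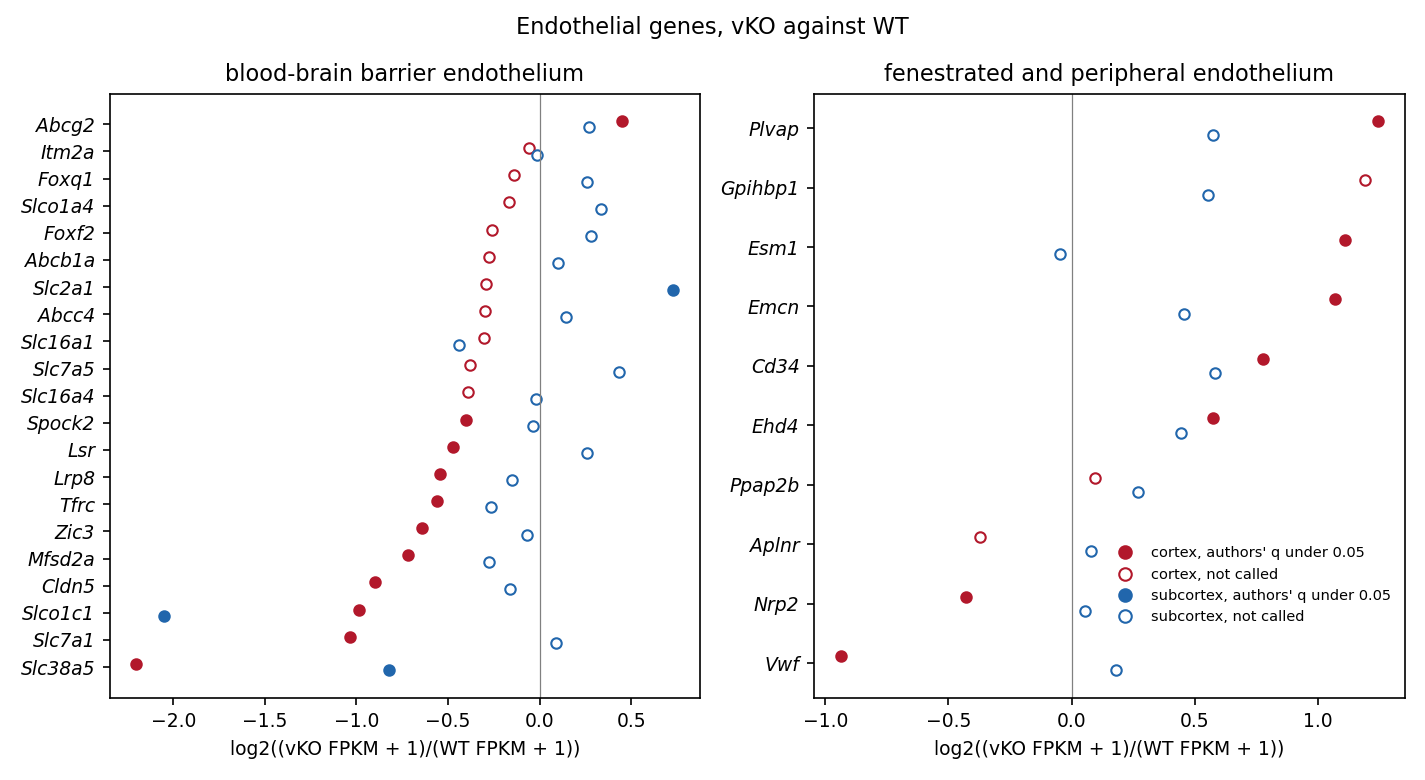
Log2 ratio of vKO over WT FPKM (each plus 1; x axis) for the genes of the barrier list and of the fenestrated and peripheral list (y axis), in cortex (red) and subcortex (blue), with filled points for genes that the authors' deposited table calls at a q-value under 0.05. In cortex 10 of 21 barrier genes were called lower and 5 of 10 fenestrated genes higher, and each point is the ratio of a vKO and a WT group value, without an error.

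Genes shared by endothelial cells of all beds went both ways in cortex. Of 19 tested, 2 rose and 4 fell by the authors' deposited table (2 and 5 adjusted over the list alone), with a median of -0.23 (percentiles 2.76 and 4.62) that was -0.01 once the length and GC trend was removed. The receptors of VEGF fell, Kdr from 11.0 to 5.30 FPKM (-0.93) and Flt1 from 3.42 to 1.96 (-0.58), while Clec14a rose from 2.65 to 4.22 (0.52). Of 12 tested targets of beta-catenin signalling 1 rose and 4 fell by the authors' deposited table (1 and 5 adjusted over the list alone), with a median of -0.28 (percentiles 2.24 and 1.90) that was -0.09 with the trend removed. Apcdd1, an inhibitor of Wnt signalling, fell from 19.9 to 13.2 FPKM (-0.56; -0.07 with the trend removed). Lef1, a transcription factor of the pathway, fell from 2.57 to 1.36 FPKM (-0.60) and the Wnt deacylase Notum from 1.30 to 0.425 (-0.69), while Fgfbp1 rose from 2.89 to 7.95 (1.20). Among 10 tested genes of tip cells and sprouting, 2 rose in the authors' deposited table (2 and 0 lower adjusted over the list alone): Esm1, from 0.303 to 1.81 FPKM (1.11), which the fenestrated list also holds, and Kcne3, listed at 0 in WT and at 3.99 in vKO. Their list's median was -0.22 (percentiles 8.03 and 8.61).

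Vascular basement membrane genes had a median of -0.40 in cortex (percentiles 0.07 and 33.5), and their median transcript length was 6450 bases. Of 11, 5 fell and 0 rose by the authors' deposited table, and the same numbers held adjusted over the list alone. Fn1, fibronectin, fell by 0.81 on the log2 scale, to 10.9 FPKM, and Nid1 from 10.1 to 7.10 (-0.46). With the length and GC trend removed the list's median was 0.07, and the ratios of Hspg2 and Lamc1 changed sign. Of 12 pericyte genes 1 rose and 3 fell by the authors' deposited table, with and without adjustment over the list alone. Their median was -0.05 (percentiles 45.9 and 60.5; 0.01 with the trend removed). Notch3 fell from 4.41 FPKM in WT by 0.76 on the log2 scale, and the potassium channel gene Kcnj8 rose from 3.42 to 6.01 (0.66). The contractile genes Myl9 and Acta2 rose, from 10.9 to 16.8 and from 1.58 to 2.70 FPKM, out of 3 tested smooth muscle genes (2 higher and 0 lower also adjusted over the list alone), whose median was 0.54 (percentiles 99.5 and 96.4; 0.29 with the trend removed). Of 11 tested genes of meningeal fibroblasts 3 rose and 1 fell by the authors' deposited table, again also adjusted over the list alone, and the median was 0.30 (percentiles 99.8 and 100). The proteoglycan Dcn rose from 15.4 to 22.7 FPKM (0.53), and the organic anion transporter Slc22a6 fell from 3.27 to 1.74 (-0.64).

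Erythroid, microglial, macrophage and neutrophil lists had medians above 0 in cortex, that is higher in vKO, though most tested erythroid and neutrophil genes were not called. Erythroid genes had a median of 3.43 over 9 tested members (percentiles 100 and 100; 3.13 with the trend removed, over 8 of them), of which 3 rose by the authors' deposited table and by adjustment over the list alone. In this list Hba-a2 and Hbb-bs each have an entry of their own and a part in a joint entry. The entries of the list are therefore not all separate genes. The beta-globin entry of Hbb-b1 and Hbb-bs rose from 233 to 4173 FPKM, and Alas2, the erythroid enzyme of haem synthesis, from 5.70 to 34.6. Hba-a2, picked after its values were seen, had 14.2 FPKM in WT and 613 in vKO yet a q-value of 0.643 in the authors' deposited table. Of 12 tested microglial genes 8 rose and 0 fell by the authors' deposited table (9 higher adjusted over the list alone), with a median of 0.88 (percentiles 100 and 100; 0.69 with the trend removed). Tyrobp, a signalling adaptor of myeloid cells, rose from 8.59 to 27.5 FPKM (1.57) and the complement gene C1qb from 7.55 to 20.8 (1.35). Of 13 tested macrophage, haem and iron genes 9 rose and 0 fell by the authors' deposited table (10 adjusted over the list alone), with a median of 0.80 (percentiles 100 and 100; 0.51 with the trend removed). Besides Hmox1 they included Gpnmb, from 0.289 to 3.19 FPKM (1.70), and Lgals3, from 0.885 to 4.43 (1.53). The lysozyme gene Lyz2 rose from 3.14 to 47.9 FPKM (3.56). S100a9, a calcium-binding protein of neutrophils, rose from 0.908 to 17.2 FPKM (3.25) and was the 1 called of 3 tested neutrophil genes, over all genes and over the list alone, with a median of 3.25 (percentiles 100 and 100). Of 6 tested inflammation and interferon genes 1 rose, Isg15, from 0.941 to 2.73 FPKM (0.94), by the authors' deposited table and adjusted over the list alone, with a median of 0.18 (percentiles 92.6 and 88.9).

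Hypoxia and glycolysis genes were higher as well. Of 25 tested hypoxia genes 8 rose and 2 fell by the authors' deposited table (11 and 2 adjusted over the list alone), with a median of 0.29 (percentiles 100 and 100). Vegfa, the growth factor of vessels, rose from 20.7 to 33.4 FPKM (0.66), Ddit4 from 25.4 to 49.6 (0.94) and Bnip3, which has 5 near-identical copies, from 16.8 to 41.5 (1.25). Of 17 glycolysis genes 10 rose and 0 fell by the authors' deposited table (12 adjusted over the list alone), with a median of 0.74 (percentiles 100 and 100; 0.48 with the trend removed). The lactate exporter Slc16a3 rose by 1.66 to 6.90 FPKM and Gpi1 from 47.4 to 94.1 (0.97). Gapdh, with 89 near-identical copies, rose from 2.69 to 29.3 FPKM, so the assignment of its reads is uncertain. Of 13 tested stress response genes 3 rose and 1 fell by the authors' deposited table, with and without adjustment over the list alone, and the median was 0.35 (percentiles 99.8 and 99.8; 0.07 with the trend removed). Atf3, a stress-induced transcription factor, rose from 0.206 to 1.86 FPKM (1.25). Immediate early genes numbered 3 risen and 1 fallen of 8 tested by the authors' deposited table (5 and 1 adjusted over the list alone), with a median of 0.39 (percentiles 99.9 and 99.9): Fos rose from 0.989 to 3.13 FPKM (1.05) and Npas4 fell from 1.08 to 0.479 (-0.49).

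Genes of dividing cells and intermediate progenitors were higher and several neuronal genes lower. Of 15 cell cycle genes 7 rose and 0 fell by the authors' deposited table (9 adjusted over the list alone), with a median of 0.47 (percentiles 100 and 100), among them Cdk1, from 5.32 to 9.35 FPKM (0.71). Of 6 tested intermediate progenitor genes 5 rose by the authors' deposited table and by adjustment over the list alone, with a median of 0.53 (percentiles 100 and 100), and Eomes, their marker transcription factor, rose from 5.48 to 8.18 FPKM (0.50). Inhibitory neuron genes had 4 of 10 fallen and 0 risen by the authors' deposited table and adjusted over the list alone, with a median of -0.26 (percentiles 0.82 and 0.07; -0.40 with the trend removed). Gad1 and Gad2, the enzymes of GABA synthesis, fell from 39.9 to 26.5 and from 18.5 to 11.3 FPKM, and Lhx6 from 17.5 to 10.3. Of 12 genes of cortical excitatory neurons 1 rose and 4 fell by the authors' deposited table (1 and 5 adjusted over the list alone), with a median of -0.24 (percentiles 0.46 and 4.12) that was -0.08 with the trend removed. Rorb fell from 7.82 to 4.70 FPKM (-0.63), while Neurod6 rose from 98.3 to 168 (0.77). Of 11 tested genes of subcortical neurons 3 fell by the authors' deposited table and adjusted over the list alone, with a median of -0.34 (percentiles 0.97 and 0.245), and Tcf7l2 fell from 4.71 to 1.07 FPKM (-1.47). Radial glia and astrocyte genes went both ways, 3 of 15 up and 2 down by the authors' deposited table and adjusted over the list alone, with a median of 0.15 (percentiles 81.6 and 82.3): Vim rose from 99.9 to 171 FPKM (0.77) and Tnc fell from 52.5 to 32.2 (-0.69). No oligodendrocyte gene of 8 tested and no choroid plexus gene of 8 tested was called in the authors' deposited table or adjusted over the list alone, with medians of 0.02 (percentiles 68.7 and 86.5) and -0.10 (percentiles 30.4 and 9.62; -0.30 with the trend removed). Olig1 had a log2 ratio of 0.09 and 22.5 FPKM in vKO, and Ttr had 504 FPKM in WT and 485 in vKO. Of 8 metalloproteinases and inhibitors related to Reck 1 fell, Mmp9, from 2.36 to 0.984 FPKM (-0.76), by the authors' deposited table and adjusted over the list alone, with a median of -0.19 (percentiles 11.8 and 9.57).

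Among the largest changes outside the lists, Rprl3, an RNase P RNA-like gene, rose from 4.44 to 478 FPKM and the histone gene Hist1h2bc, with 13 near-identical copies, from 69.8 to 390. Ly75, an endocytic receptor, fell from 1.89 to 0.196 FPKM (-1.27). The long genes Shank1, Pclo and Nrxn3, of synapses, fell to 7.96 FPKM (-1.30), from 18.8 to 7.38 and from 36.5 to 14.5, and the histone methyltransferase gene Kmt2d from 10.3 to 3.58.

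Transcript length and markers of sex moved with genotype in cortex. Ratios fell with transcript length, with a Spearman correlation across 13412 genes of -0.553, and genes are not independent replicates. Called genes that were higher had a median length of 1559 bases, those that were lower 6192, and those not called 3096. In the shortest decile of genes 28.4% were called higher and 0.447% lower by the authors' deposited table, and in the longest decile 0.522% higher and 46.6% lower. With 1 added to both FPKM values, 1051 cortex calls changed at least 1.5-fold, and 458 after removal of the trend, 207 higher and 251 lower. Among genes named above, the ratios with the trend removed were -0.23 for Flt1, -0.39 for Vwf, -0.27 for Notch3, -0.32 for Fn1, -0.20 for Nid1, -0.33 for Tnc and 0.24 for Myl9. Markers of sex moved too. Xist, transcribed from the inactive X of female cells, was at 0.0417 FPKM in WT and 18.6 in vKO cortex (4.23), and of 4 Y-linked genes 3 fell by the authors' deposited table, with Eif2s3y going from 30.4 to 15.8 FPKM and Kdm5d from 11.2 to 6.07. The sex-linked list, Xist among its 5 genes, had 1 risen and 3 fallen in cortex (1 and 4 adjusted over the list alone), with a median of -0.63 (percentiles 0.12 and 0.015). The labels give no sex, so sex composition and genotype overlap in this comparison.

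**Figure D2:**
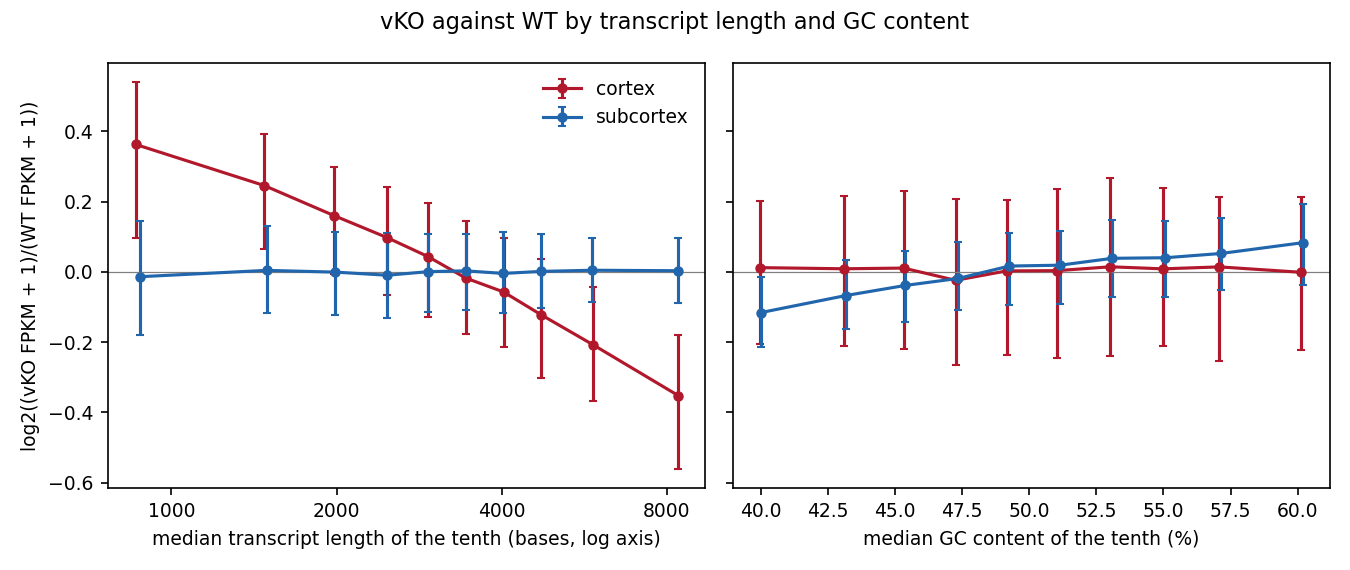
Median log2 ratio of vKO over WT FPKM (each plus 1; y axis) in deciles of transcript length (left, bases, log axis) and of GC content (right, percent), for cortex (red) and subcortex (blue), with bars from the lower to the upper quartile of genes. In cortex the median goes from 0.36 in the shortest decile to -0.35 in the longest, and in subcortex the ratio rises with GC content.

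The comparison of vKO with WT subcortex asks the same of the deeper brain. Pan-endothelial, basement membrane and choroid plexus lists were among those with medians above random lists in subcortex, though no gene of the choroid plexus list was called. Lower in vKO were 2 barrier transporters. Slco1c1 (chromosome 6, 141524386 to 141570177) fell from 10.7 to 1.82 FPKM (-2.05), and Hmox1 rose from 3.32 to 14.5 (1.84). The endothelial junction genes Pecam1 and Cdh5 rose from 5.12 to 10.1 (0.86) and from 3.62 to 6.45 FPKM (0.69). Of 13735 tested genes, 98 were called by the authors' deposited table, 62 higher and 36 lower, and all 98 changed at least 1.5-fold in the FPKM ratio without a pseudocount, 88 of them with 1 added to both values.

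Of 11 basement membrane genes 4 rose and 0 fell in subcortex by the authors' deposited table (8 higher adjusted over the list alone), with a median of 0.47 (percentiles 100 and 100; 0.38 with the trend removed). The collagen IV genes Col4a1 and Col4a2 rose from 20.6 to 37.2 (0.82) and from 13.4 to 22.1 FPKM (0.69). Of 19 tested pan-endothelial genes 2 rose and 0 fell by the authors' deposited table (8 higher adjusted over the list alone), with a median of 0.35 (percentiles 100 and 100; 0.28 with the trend removed). None of 8 tested fenestrated and peripheral genes was called in the authors' deposited table and 4 were higher adjusted over the list alone, with a median of 0.36 (percentiles 100 and 100): Plvap, named for comparison with cortex, had 2.15 FPKM in WT and 3.69 in vKO. Barrier genes had a median of -0.01 (percentiles 37.8 and 38.9; 0.06 with the trend removed), with 1 risen and 2 fallen of 21 by the authors' deposited table (2 and 3 adjusted over the list alone). Slc2a1 rose from 12.8 to 21.9 FPKM (0.73) and Slc38a5 fell from 4.21 to 1.94 (-0.82), while Cldn5, named for comparison, stood at 42.2 in WT and 37.6 in vKO. Of 11 tested pericyte genes 1 rose, Pdgfrb, from 3.73 to 5.96 FPKM (0.56), by the authors' deposited table (4 adjusted over the list alone), with a median of 0.21 (percentiles 99.9 and 99.8; 0.14 with the trend removed). Acta2 rose from 1.14 to 2.77 FPKM (0.82), the 1 called of 3 tested smooth muscle genes, also over the list alone, with a median of 0.69 (percentiles 100 and 99.6). Of 8 tested tip cell genes 1 rose, Igfbp3, from 7.97 to 18.6 FPKM (1.13), by the authors' deposited table (1 higher and 1 lower adjusted over the list alone), with a median of 0.13 (percentiles 95.6 and 92.9). Of 13 tested beta-catenin targets 1 rose, Sox17, from 0.839 to 2.06 FPKM (0.74), by the authors' deposited table (2 higher and 1 lower adjusted over the list alone), with a median of -0.01 (percentiles 46.6 and 32.7). Of 11 tested meningeal genes 2 fell, Slc22a6, from 1.91 to 0.966 FPKM, and Crabp2, from 17.0 to 9.94, by the authors' deposited table (1 higher and 2 lower adjusted over the list alone), with a median of 0.12 (percentiles 97.4 and 97.0).

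Of 12 tested macrophage, haem and iron genes 2 rose in subcortex, Hmox1 and the haemoglobin receptor Cd163, the latter from 0.404 to 1.15 FPKM, by the authors' deposited table and adjusted over the list alone, with a median of 0.03 (percentiles 70.1 and 79.3). None of 11 tested microglial genes was called there by either count, with a median of 0.02 (percentiles 62.0 and 45.7), and C1qa stood at 14.6 FPKM in WT and 20.1 in vKO. Erythroid genes had 0 of 8 called by either count and a median of 0.27 (percentiles 100 and 99.6), with the entry of Hbb-b1 and Hbb-bs at 403 in WT and 482 in vKO. Neutrophil genes had 0 of 2 called (1 higher adjusted over the list alone) and a median of 1.28 (percentiles 99.8 and 98.3). Of 5 tested inflammation genes 1 rose, the acute-phase gene Serpina3n, from 1.23 to 3.32 FPKM (0.96), by the authors' deposited table (2 adjusted over the list alone), with a median of 0.09 (percentiles 78.9 and 78.1). The metallothioneins Mt1 and Mt2 rose from 57.5 to 128 and from 13.2 to 41.3 FPKM, the heat shock gene Hspb1 from 2.60 to 6.32 and Avp, the precursor of vasopressin, from 10.1 to 26.3. Rprl3 rose from 7.27 to 1268 FPKM, and the small RNA entries Mir6236 and Rnu11 fell from 14379 to 990 and from 3280 to 1300.

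No hypoxia gene of 24 tested was called in subcortex by the authors' deposited table (1 higher adjusted over the list alone), and the median was 0.01 (percentiles 62.1 and 70.5): Bnip3 had 33.7 FPKM in WT and 34.1 in vKO. Of 16 tested glycolysis genes 2 fell, Pgam1, from 54.5 to 35.9 FPKM (-0.59), and Gapdh, from 19.6 to 4.18, by the authors' deposited table and adjusted over the list alone, with a median of 0.00 (percentiles 52.4 and 9.63; -0.03 with the trend removed). No member of the neural, progenitor, cell cycle, oligodendrocyte, choroid plexus, stress, immediate early and metalloproteinase lists was called in subcortex by the authors' deposited table, and adjusted over the list alone 3 choroid plexus genes, 1 excitatory neuron gene and 1 immediate early gene were higher. Medians were 0.10 for radial glia and astrocytes (percentiles 98.7 and 98.4), 0.07 for the cell cycle (89.1 and 92.5) and 0.11 for intermediate progenitors (90.7 and 87.6). They were 0.06 for excitatory neurons (percentiles 82.7 and 71.7), 0.05 for inhibitory neurons (77.7 and 70.3) and -0.04 for subcortical neurons (26.3 and 52.2). The oligodendrocyte lineage had -0.01 (percentiles 49.0 and 27.3), the choroid plexus 0.23 (99.8 and 99.8), stress genes -0.01 (45.1 and 45.9; 0.01 with the trend removed), immediate early genes 0.13 (90.6 and 81.5) and metalloproteinases 0.15 (98.0 and 97.2). Ttr, the main transcript of choroid plexus, had 484 FPKM in WT and 719 in vKO subcortex. Outside the list, Wfikkn2 and Slc4a5, genes of choroid plexus picked after their values were seen, rose from 1.89 to 3.92 and from 0.602 to 1.28 FPKM by the authors' deposited table. Xist stood at 0.0369 FPKM in WT and 10.2 in vKO (3.43), and the sex-linked list had 1 risen and 2 fallen of 5 by the authors' deposited table (1 and 4 adjusted over the list alone) and a median of -0.54 (percentiles 0 and 0). The correlation of ratios with length was 0.0209 across 13561 genes and that with GC content 0.311. At a q-value under 0.01 the authors' deposited table calls 0 subcortex genes, against 867 at an unadjusted p-value under 0.05, and the lowest q-value there is 0.0104.

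**Figure D3:**
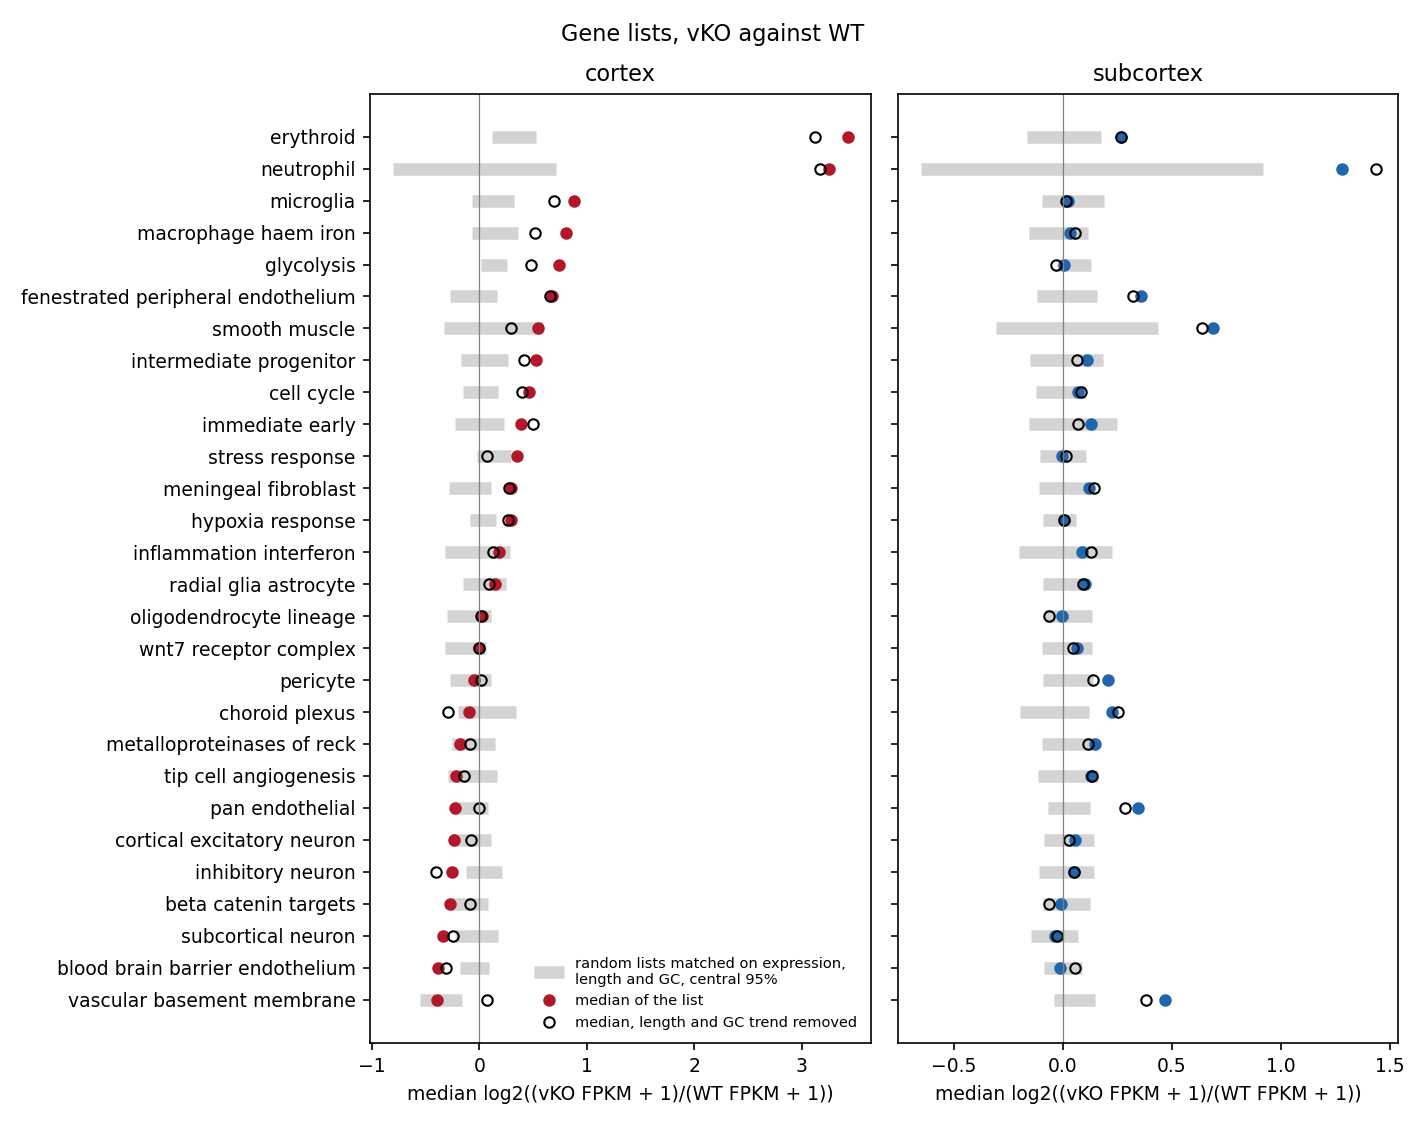
Median log2 ratio of vKO over WT FPKM (each plus 1; x axis) of the 28 fixed gene lists without the sex-linked one (y axis), for cortex (red) and subcortex (blue), with open points after removal of the length and GC trend and grey bars for the central 95% of random lists matched on expression, length and GC. In cortex the erythroid median is 3.43 and the barrier median -0.39, and in subcortex the basement membrane median is 0.47.

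Between the tissues, calls in the same direction were more frequent than independent lists would share. Of 13167 genes tested in both, 23 were higher in both tissues (4.51 for independent lists) and 12 lower in both (3.73), by the authors' deposited tables. The labels do not say whether the tissues come from the same brains, and markers of sex moved in both. Shared animals or a shared sex composition could raise these numbers, so they do not by themselves show a shared effect of genotype. Lower in both were the transporters Slco1c1, Slc38a5, Slc22a6 and Slc22a8, the last from 3.55 to 0.955 FPKM in cortex and from 2.97 to 1.09 in subcortex, with Ly75 and the glycine receptor gene Glra2 among the rest. Higher in both were Hmox1, Mt1, Mt2, Lyz2, Cd163, Acta2 and the oxidoreductase gene Nqo1, which went from 1.96 to 3.71 FPKM in cortex and from 3.26 to 6.38 in subcortex. Among genes higher in both, some have near-identical copies, such as Lyz2 with 1, Hist1h2ac with 12, Hist1h2bc with 13 and Hist1h2bf with 14. A further 7 genes were higher in cortex and lower in subcortex by the authors' deposited tables (2.66 for independent lists), among them Gapdh, Hist1h3c, Rpl17 and Rpl21, which have near-identical copies, and 3 were the reverse (6.32), namely Col4a2, Hspg2 and Zbtb16. With the length and GC trend removed the cortex ratios of these 3 went from -0.43 to -0.08, from -0.41 to 0.14 and from -0.39 to -0.21, so for Hspg2 the opposite direction is lost and for Col4a2 little of the cortex fall is left. Xist is among the genes higher in both, and of the 12 lower in both Slc38a5, Glra2, Cdr1 and Col4a6 lie on X and Eif2s3y and Uty on Y. The labels give no sex, so the falls of Eif2s3y and Uty carry that uncertainty. For the falls of Slc38a5, Glra2, Cdr1 and Col4a6, 4 genes known to escape X inactivation gave no common direction in cortex, with 1 called higher and 1 lower. In subcortex 0 of them were called. The medians of these 4 were 0.158 in cortex and 0.198 in subcortex, at the 62.0th and 99.2nd percentiles of expression-matched lists. An effect of sex on the falling genes of X was not tested. Genes named in this paragraph were read from the overlap after it was computed, and part of them lie outside the rule for named genes. Across 13115 genes the ratios of the 2 tissues correlated with a Spearman coefficient of 0.059 and a Pearson coefficient of 0.0688, and genes are not independent replicates. No interaction was tested, so a call in one tissue and not in the other does not show a difference between them.

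In cortex 19 of the 28 lists without the sex-linked one lay outside the central 95% of expression-matched lists, 13 above and 6 below, and 16 did so on the same side with length and GC matched. In subcortex 10 did, all above, and 9 with length and GC matched. These percentiles describe 1 value per gene and group and carry no replicate error.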

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

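Thresholds for these entries, an FPKM of at least 5 in one group and at least 4 times the other, were chosen after the data were seen. Some entries that the authors' test skipped, which the comparisons therefore do not use, were listed higher in vKO than in WT, and others the reverse. Most of them were marked as too low or as lacking data, so their values are uncertain. In cortex 23 such entries had at least 5 FPKM in vKO and at least 4 times the WT value, 22 of them microRNA or small nucleolar RNA genes, and 22 were listed at 0 in WT. In subcortex there were 53, of which 44 were microRNA or small nucleolar RNA genes and 52 were listed at 0 in WT. The opposite pattern was found in 40 entries in cortex and 23 in subcortex. Mir5133 was listed at 0 in WT and 83.6 FPKM in vKO cortex, and at 60.9 in WT and 0 in vKO subcortex. Entries marked as too deep to estimate include Gphn, at 23.0 FPKM in WT and 0 in vKO cortex and at 0 and 32.2 in subcortex. No explanation was tested for these values.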

How the results depend on the processing

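The trend removal, the exclusion of genes with copies or on X and Y, and matching on length and GC were chosen after the data were seen, and the other alternatives before. In cortex the number of calls by the authors' deposited table was 2645, with 3539 at a q-value under 0.1, 2640 with an FPKM filter, 2127 without genes that have a near-identical copy and 2528 without genes on X and Y. It fell to 1534 at a q-value under 0.01 (545 higher, 989 lower) and to 1520 with a 1.5-fold minimum on the FPKM ratio without a pseudocount (591 and 929), which follows from stricter thresholds. With 1 added to both values the minimum left 1051, and 458 after removal of the length and GC trend, which changed the sign of 113 cortex calls. Over the 8 criteria for copies, 2067 to 2418 cortex calls and 66 to 83 subcortex calls were left. In subcortex the count was 98, with 125 at a q-value under 0.1, 98 with the filter and with the fold minimum, 66 without copies (19 lower against 36) and 89 without X and Y. With 1 added to both values the fold minimum left 88, and 83 after removal of the trend. At a q-value under 0.01 it was 0, since the lowest q-value there is 0.0104.

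The rank correlation of the tissues' ratios, 0.059, was 0.0687 with a pseudocount of 0.1, 0.00764 with an FPKM of at least 5 and 0.169 with the trend removed in both. For the last pair the cause was not tested. Of the cortex genes named as called and the cortex lists outside the central 95% of expression-matched lists, removal of the trend turned 5 positive: the basement membrane median (from -0.40 to 0.0654), Ptprb (0.0129), Cspg4 (0.0834), Hspg2 (0.138) and Lamc1 (0.0891). Their transcripts are long, so the subtracted trend shifts them upward by construction. Among the other values of named genes and lists, and the counts by direction, 277 held and 32 moved under the alternatives fixed before, with 6 counts falling by over 1.5 times, and under the added ones 230 held, 15 moved and 3 counts fell. A named gene held where it stayed within 1.5-fold, and a list where its median stayed within 1 SD of its random lists. The ratio of Reck held in both tissues under each alternative run.

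No paired analysis was possible because the tables carry 1 value per group and no replicate numbers. For the same reason the replicates left out in turn, quantile normalization, size factors per sample, a pseudocount of 0.01 and other filters in a model of samples, a fit of all 12 samples, set tests with a model, the tissue interaction and counts from other tools were not run. The median-ratio rescaling of group values shifts cortex ratios by 0.00522 and subcortex ratios by -0.00114. The depth is unknown, so it is not known which differences these libraries could have shown.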

Other observations

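The families below and the tests of fewer endothelial cells and of Xist alone were chosen after the result was seen. Gene families taken from symbol patterns are given with medians followed by percentiles as for the lists, and with calls of the authors' deposited table throughout. The values of this paragraph are those of cortex. Ribosomal protein genes had a median of 0.54 (percentiles 100 and 100; 0.21 with the length and GC trend removed), with 64 of 87 risen and 2 fallen by the authors' deposited table. Near-identical copies occur among them too, 28 for Rpl17 and 66 for Rpl21. Histone genes, many with near-identical copies, had 49 of 58 risen and a median of 0.87 (100 and 100; 0.47 with the trend removed). Of 74 respiratory chain genes 31 rose, with a median of 0.38 (99.9 and 57.6; 0.06 with the trend removed), and of 37 proteasome genes 16 rose and 1 fell, with a median of 0.37 (99.9 and 96.6; 0.12 with the trend removed). The 3 metallothioneins rose, with a median of 2.08 (100 and 100; 1.71), and of 21 heat shock genes 3 rose and 1 fell, with a median of 0.21 (97.7 and 97.4; 0.09). Genes of voltage-gated and ligand-gated channels had 47 of 92 fallen and 3 risen by the authors' deposited table, with a median of -0.42 (0 and 0; -0.23 with the trend removed), and the NMDA receptor gene Grin2b fell from 50.6 to 24.1 FPKM. Semaphorin, plexin, ephrin and netrin genes had 27 of 64 fallen and 2 risen, with a median of -0.33 (0 and 0.01; -0.06), and protocadherin genes 5 of 68 fallen, with a median of -0.42 (0 and 0; -0.31). Small nucleolar RNA genes had 1 of 61 called, with a median of 0.06 that was -0.36 with the trend removed (0 and 0).

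In subcortex metallothioneins had 2 of 3 risen by the authors' deposited table and a median of 1.14 (percentiles 100 and 100; 1.15 with the trend removed). Histone genes had 4 of 56 risen and 2 fallen (median 0.14; percentiles 100 and 100; 0.10), and small nucleolar RNA genes had 0 of 53 called and a median of -0.64 (0 and 0; -0.58). Heat shock genes had 1 of 20 risen and a median of -0.11 (0.78 and 1.41; -0.14), and ribosomal protein genes 2 of 87 fallen and a median of -0.02 (20.3 and 65.8) that was 0.02 with the trend removed. Respiratory chain, proteasome, protocadherin, channel and semaphorin-group genes had none called, with medians of -0.02 (22.9 and 68.1), 0.01 (59.3 and 87.8), 0.04 (92.1 and 91.3), -0.02 (15.4 and 10.8) and 0.06 (99.7 and 91.5).

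Long transcripts were lower in vKO cortex. The tables argue against GC content as the carrier of this trend, since the partial rank correlation with length given GC was -0.571, and against a genotype effect on long transcripts of the same size in both tissues, since the correlation was 0.0209 in subcortex. A length bias between the cortex groups is a candidate explanation, with a correlation of -0.553 where it needed one below -0.2, and with the longest transcript of any type the value was -0.527. That test shows the trend and not its origin: RNA quality or library preparation in the cortex groups and an effect of genotype in cortex, where long genes include those of channels and synapses, stay open, as no value per library was used.

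Barrier genes were lower in vKO cortex, and transcript length as the whole cause is argued against, since the barrier median lay at percentile 0 of random lists matched on expression and length. Fewer endothelial cells may account for the fall and cannot be told apart from a change within the cells: the pan-endothelial median exceeded the barrier median by 0.161, at the 93.7th percentile of pairs of random lists matched on expression and at the 97.1st with length and GC matched, both within the central 95%. With the length and GC trend removed the medians were -0.01 and -0.31 and the difference 0.303, beyond the upper limits of the central 95% in both matchings (0.167 and 0.160), which speaks against equal loss, but a 95% interval from resampling the members ran from -0.07 to 0.58, so the lists' own spread keeps it open. The first rule, on expression matching alone, would have kept this explanation, and it was changed after values were seen, first to ask for both matchings, then to ask for both with the trend removed and, before the interval was seen, for an interval without 0. Fenestrated genes had a median of 0.68 in the same tissue, so a loss of cells would need another change beside it.

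Xist was higher and Y-linked genes were lower in both vKO groups. A change of Xist alone is argued against, since the median of 4 Y-linked genes was -0.71 in cortex and -0.59 in subcortex, at percentiles of 0.08 and 0 among random lists. A larger share of female tissue in the vKO groups is a candidate explanation: 4 genes known to escape X inactivation had medians of 0.158 in cortex and 0.198 in subcortex, at the 62.0th and 99.2nd percentiles, where the test asked for both above 0 and one above the central 95%. Of these 4, 1 was called higher and 1 lower in cortex. Xist stood at 0.0417 FPKM in WT cortex and 0.0369 in WT subcortex, against 18.6 and 10.2 in vKO. Eif2s3y kept 15.8 FPKM in vKO cortex and 13.3 in vKO subcortex, from 30.4 and 27.6 in WT. Read as markers of sex, these are values of WT groups with little or no female tissue and vKO groups of both sexes. Each vKO to WT ratio would then compare groups of unlike sex. The labels give no sex, so an effect of sex on other genes and an effect of genotype stay open together.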
